A study of Mus musculus with 15 samples.

How the data were processed

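The samples were CD8 T cells sorted from Balb/c mice, and their gene expression was measured on microarrays. Per the labels' protocols, BM and LN were CD3 and CD8 positive T cells that bound a pentamer of the major histocompatibility molecule H2-Kd carrying a peptide of the HIV Gag protein p24. A pentamer is a fluorescent reagent that labels T cells whose receptor recognises that peptide. BM cells came from bone marrow and LN cells from the draining lymph nodes, taken 5 days after mice had received MVA-HIV gag, a modified vaccinia virus that carries the gag gene, into the skin. NTc were CD8 T cells sorted by surface markers, among them intermediate CD44, from lymph nodes of mice that had not been injected. Each group held 5 samples with 1 array each, 15 arrays in all.

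Cells were lysed and their mRNA was isolated with magnetic beads, reverse transcribed and amplified by global PCR with the SuperAmp procedure, whose details the maker does not disclose, per the labels' protocols. From each sample 250 ng of amplified cDNA was labelled with Cy3, a single dye. The series' design text says that RNA was pooled from 3 independent experiments of 5 mice each. It does not say whether the 5 samples of a group came from separate pools, so p-values here measure only the spread between these samples, which may be technical.

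The scanner files were made with Agilent Feature Extraction 10.7.3.1, per the file headers, and name the mouse genome build mm9. The deposited scanner values are intensity values on a linear scale: a processed signal with background subtracted, the mean signal of the spot, the median of its local background, and flags for spots that are well above background, saturated or outliers. The scanner files carry no normalization between arrays. A value table of the whole series was deposited as well. The deposited values are on a log2 scale, since each column correlated across probes with the log2 processed signal of its own array at r of 0.993 or more, with the same direction. Column medians lay between 6.12 and 6.13 and 75th percentiles between 8.75 and 8.76, the near-equal quartiles that quantile normalization leaves. The method of that normalization is not given in the sources used here, and the values are not centred per gene.

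Each array held 62976 spots, of which 59305 were not control spots, and these carried 55681 different probes of 60 bases. No spot was saturated. Outlier spots, 143 to 262 per array, were left out. Spots of 1 probe were averaged on the log2 scale. The main values were log2 processed signal minus the 75th percentile over the probes of each array, so a value of 0 is the 75th percentile of the array and a difference of 1 is a doubling of signal. A probe was kept if it was well above background on at least 4 of the 5 arrays of at least 1 group, which left 35978 probes, and 3 of these were left out for missing values. For each gene name in the files the kept probe with the highest mean over all arrays was used, giving 25575 features. Through accession or symbol, 14795 of these (57.8%) matched a gene in a RefSeq table of assembly GRCm38.p6, which was used only for names and to match the gene lists. Probe coordinates are those in the files, in mm9, and no annotation of that build was used here to place probes in exons or untranslated regions. Names are those of the array's design and some are old.

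Levels of different probes were not set against each other as amounts of RNA. Where a probe was not well above background on any array of a group, the level there is only a bound, and the difference is given as at least N-fold. That bound is the bright group's mean against the mean, in the dim group, of the higher of the probe's own value and the lowest signal among probes well above background on each array. Where some but not all arrays of a group were well above background, the measured values were used and the number of such arrays is given. Such a difference can be too large, so it was also computed with every value under its array's floor raised to that floor, which was added after the data were seen. The floor is that lowest signal. A bound allows for undetected signal but not for the spread between arrays, so leaving out an array can lower it. The bounds hold for the main values only: after normexp correction, where the offset raises dim signal, the fitted fold lay below the bound for 14 of 15 such differences.

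Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 linear model over all 15 arrays so that the 3 groups shared 1 estimate of the spread. P-values were adjusted over all features by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. All limma tests were two-sided. The comparisons were BM with LN, BM with NTc and LN with NTc. Samples of different groups share replicate numbers, but no label says that a number pairs them, and the main model held no pairing.

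Gene lists were fixed before the data were examined. There were 18 lists of genes of T cell biology and metabolism: effector molecules, naive and resting T cells, effector and memory transcription factors, inhibitory and costimulatory receptors, chemokine receptors, integrins and homing, cytokines and cytokine receptors, DNA replication, mitosis, glycolysis, oxidative phosphorylation, fatty acid oxidation and lipid synthesis, hypoxia response, type I interferon response, immediate early and NF-kB targets, heat shock and unfolded protein response, apoptosis regulators, ribosomal proteins, and TGF-beta response and tissue residence. A further 13 lists held markers: T cell identity, CD4 and regulatory T cells, NK and innate lymphoid cells, B cells, plasma cells, neutrophils and granulocyte precursors, monocytes and macrophages, dendritic cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, haematopoietic progenitors, and stroma with endothelium. The 31 lists were tested with limma's camera, which compares a list with all other features, at a preset correlation between genes of 0.01 and also with a correlation estimated per list. They were also tested with fry, which asks whether a list's members change without reference to other genes. For camera and fry, missing values of 209 features were replaced by the group mean.

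Genes to be named were chosen by a rule fixed before the data were examined. It took up to 12 features per comparison and direction past the threshold, with groups that did not overlap and the probe above background on all arrays of the higher group. Where fewer passed, as in every comparison here, it took the features with the lowest unadjusted p up to 5 per direction, without those further criteria and stated as not past the threshold. Members of the fixed lists and genes of the sorting markers, among them Cd8a, Cd8b1, Cd3e and Cd44, could also be named. Some genes that the rule takes are not reported here, and no others were taken in their place. Of each list, the member with the lowest unadjusted p in each direction is named where that p was under 0.03, a limit set after the values were seen. Any other gene named was chosen after its values were seen, and this is stated.

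The arrays came from 2 slides. Slide 1 held the 5 LN arrays and BM replicates 1 to 3, and slide 2 held BM replicates 4 and 5 and the 5 NTc arrays. LN and NTc were never on the same slide. Comparisons were repeated with slide as a fixed term, with slide as a random block, and within a slide where it held both groups. With slide as a fixed term the LN and NTc difference rests on the BM arrays to link the slides. Other alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, scaling to the 75th percentile of probes above background on all 15 arrays, no filter, a stricter filter, the mean of a gene's probes, every probe on its own, the deposited value table, the replicate number as a block, only the arrays of 2 groups, eBayes with trend and robust settings, array weights, a minimum log2 change of 1, and leaving out each array. Alternatives added after the data were seen were centring of probes with the same count of G and C bases, only probes with fewer than 24 G or C bases, lists tested over every probe, leaving out the 2 least correlated arrays, and the brightness of each array as a covariate. P-values adjusted over a list alone were recomputed under other scalings, slide as a fixed term and leaving out each array, which was also added after the data were seen.

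The fit was tested on simulated data with 25366 features and 15 arrays. These had the features' own means and limma's spread, which is drawn toward a value common to all features. Features were drawn independently and without a detection floor, so recovery on the real arrays may be lower. In the BM with LN simulation 0% of changes of 2-fold, 18.0% of 4-fold, 60.8% of 8-fold and 76.8% of 16-fold were recovered. In the BM with NTc simulation these shares were 1.2%, 19.6%, 57.2% and 79.2%, and for LN with NTc 0%, 17.6%, 58.8% and 80.8%. Of the calls in these 3 simulations, 3.71%, 6.43% and 5.76% were features that had not been changed. A list shifted by 1 on the log2 scale was called by camera in 5 of 5, 4 of 5 and 5 of 5 simulations, with 0 other lists called. The number of arrays limits the precision of every comparison. Plots were made with matplotlib 3.10.9 in Python 3.11.15.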

Results

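Gene expression was measured in CD8 T cells of Balb/c mice, an inbred strain, on 15 single-colour microarrays. The BM group held 5 samples of bone marrow T cells and the LN group 5 samples of draining lymph node T cells, both sorted for binding a peptide of the HIV Gag protein after injection of a viral vector carrying that antigen. The NTc group held 5 samples of lymph node T cells from mice without injection. The series' title sets bone marrow against lymph node, and the labels call the NTc mice naive. Signal was the brightness of 60-base probes after amplification of the cells' mRNA. The 75th percentile of signal over spots lay between 234.7 units in NTc replicate 1 and 624.4 units in BM replicate 1. The share of probes well above background lay between 55.6% in NTc replicate 5 and 71.2% in BM replicate 1. The arrays' number limits the precision of every comparison, and the median 95% confidence interval of a difference was 1.28 log2 units to either side, or 2.43-fold.

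Levels are given below as log2 units relative to each array's 75th percentile, as mean ± SD with n = 5 per group. Across the 25575 features, levels on different arrays correlated at a median r of 0.829, with a range of 0.753 to 0.865, where features are not independent replicates. LN and NTc arrays correlated more within groups (mean r of 0.833) than between them (0.820), with an exact one-sided p of 0.0159 over 126 splits and an adjusted p of 0.0476 over 3 comparisons. For BM and NTc the means were 0.829 and 0.821, with an exact p of 0.0476 and an adjusted p of 0.0714. For BM and LN they were 0.831 and 0.829, with an exact p of 0.214, raw and adjusted. Taken by slide, without regard to group, r was higher by 0.0116 within than between the 2 slides (permutation p of 0.00083). All LN arrays lay on slide 1 and all NTc arrays on slide 2. The parting of LN from NTc therefore cannot be told apart from a parting of the slides. Within the BM group alone the 3 arrays of slide 1 and the 2 of slide 2 differed by 0.0139, with an exact p of 0.1, the smallest that 10 splits can give.

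Of genes behind the sort, Cd44, an adhesion receptor of activated T cells, had levels of 4.57 ± 0.18 in BM, 4.83 ± 0.20 in LN and 4.56 ± 0.37 in NTc. Cd3e, a chain of the T cell receptor complex, had 3.02 ± 1.13, 3.23 ± 0.74 and 4.02 ± 1.06. Cd8a had -2.20 ± 1.60, -1.62 ± 3.48 and -1.69 ± 1.94, and Cd8b1 had -3.68 ± 0.37, -3.71 ± 0.83 and -3.58 ± 0.56. Between 4 and 5 arrays per group were well above background for these CD8 genes. None of these 4 genes passed the threshold in any comparison. The lowest limma adjusted p among them was 0.719, for Cd3e in LN against NTc, where the log2 difference was -0.79 (95% confidence interval -2.09 to 0.51). It lay between -1.06 and -0.45 when 1 array was left out. With slide as a fixed term it was 0.33, and the small differences of Cd8a, Cd8b1 and Cd44 also took the other sign under some settings.

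**Figure D1:**
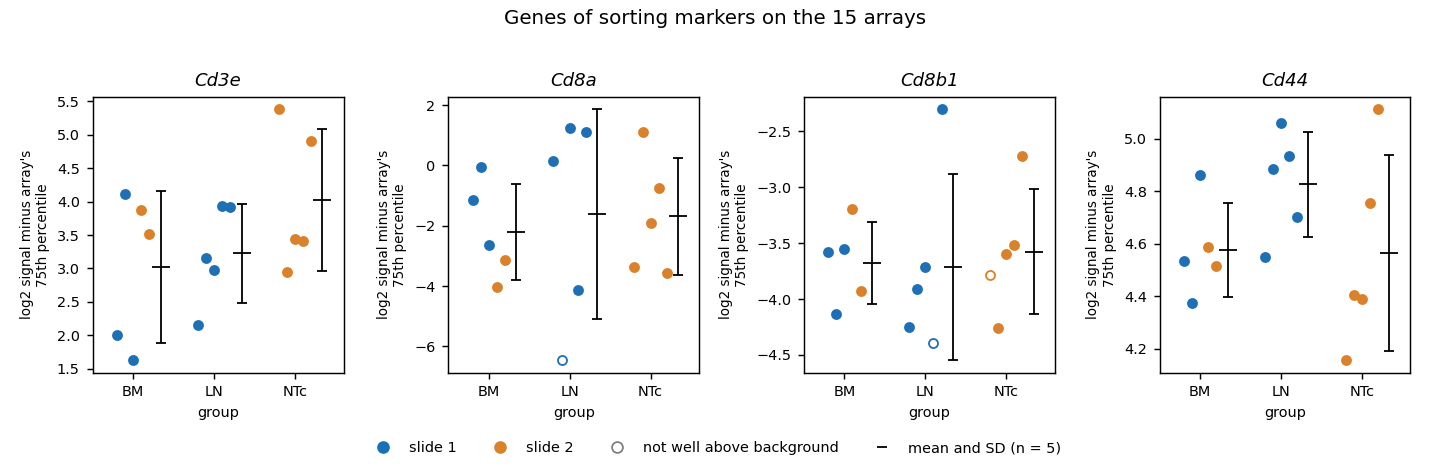
Level of 4 genes behind the cell sort on each array (vertical axis, log2 units relative to the array's 75th percentile) in the BM, LN and NTc groups. Points are arrays, coloured by slide and open where the probe was not well above background, and bars are the mean and SD of 5 arrays. The groups overlap for each gene, and Cd8a spans the widest range.

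Bone marrow and lymph node T cells of the same specificity were compared first. The genes with the lowest p included Eif4ebp3, a repressor of translation (18:36825278-36825337 in mm9), with -1.68 ± 1.54 in BM and -4.59 ± 0.92 in LN, a log2 difference of 2.91 (95% confidence interval 1.5 to 4.31). Its probe was well above background on 2 of the 5 LN arrays, and with lower values raised to each array's floor the difference was 2.46. Esrrb, an orphan nuclear receptor (12:87862509-87862568), went the other way with -0.49 ± 0.76 in BM and 1.43 ± 0.51 in LN, a difference of -1.92 (-2.91 to -0.94). Gsto2, a glutathione transferase, had -1.32 ± 0.36 in BM and -3.06 ± 0.45 in LN. None of these differences passed the threshold, and each had a limma adjusted p of 0.952. Of 25575 features 0 were called by limma, with 1268 (4.96%) at an unadjusted p under 0.05, where chance gives 1278.75. Of those, 642 were higher in BM and 626 in LN, a share higher in BM of 50.6% that was 43.4% scaled to the median and 58.3% scaled to probes above background on all arrays. The 2 groups did not overlap for 168 features (0.661%), where chance gives 0.794%.

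The other features with the lowest p on the BM side were Hrh2, a histamine receptor, with a log2 difference of 4.26, Hoxb6, a homeobox gene, with 2.70, and Slc43a2, an amino acid transporter. The Slc43a2 probe was not well above background on any LN array, and its level was at least 1.81-fold higher in BM. On the LN side were Peg3, an imprinted zinc finger gene, at least 3.25-fold higher in LN (5.75-fold without LN replicate 5 and 2.43-fold without LN replicate 2) with 4 LN arrays and 0 BM arrays well above background, Ppnr with -2.38, Olfr543, an olfactory receptor, with -1.99, and Map1lc3a, a gene of autophagy, with -1.38. All 7 had a limma adjusted p of 0.952 as well.

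The gene lists held members on both sides. Of the receptors that inhibit or costimulate T cells, 4 of 12 measured members had a positive BM minus LN difference, with a list median of -0.30. Its lowest-p member was Tnfrsf4, which encodes OX40, with -0.17 ± 0.78 in BM and 1.29 ± 1.25 in LN, where LN replicate 4 stood apart at 3.48. Of the heat shock and unfolded protein genes 16 of 24 were positive, with a list median of 0.27, and the chaperone gene Hspa1a had 0.09 ± 0.80 in BM and -1.78 ± 1.10 in LN. Of the DNA replication genes 7 of 20 were positive. Among them Mcm7, a part of the replication helicase, had a difference of 2.99 (0.97 to 5.00), while Mcm6 of the same helicase had -1.32 (-2.41 to -0.23). Glycolysis had 10 of 17, with Tpi1 at 3.55 ± 1.54 in BM and 1.72 ± 0.80 in LN, and T cell identity had 5 of 17, with Thy1 at 2.90 ± 0.46 and 1.73 ± 0.36, where the groups did not overlap.

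In the remaining lists, positive members were 8 of 22 for effector molecules, 7 of 16 for naive and resting T cells, 13 of 23 for effector and memory transcription factors, 16 of 27 for homing receptors and 12 of 26 for cytokines and their receptors, where Socs2 had 3.55. They were 14 of 28 for mitosis, with Ccna2 at least 1.34-fold higher in BM (1.06-fold without BM replicate 3 and 1.65-fold without BM replicate 2), 18 of 36 for oxidative phosphorylation, 12 of 23 for fatty acid and lipid genes, with Fasn at 1.23, and 6 of 13 for hypoxia. For type I interferon they were 18 of 32, for immediate early and NF-kB genes 6 of 25, for apoptosis 9 of 17 and for TGF-beta and residence 3 of 9. For ribosomal proteins they were 28 of 53, where Rps14 had 2.27, with BM replicate 1 apart at 1.37, and Rps4x had -1.96. Among the genes named in this comparison, 2 LN arrays were well above background for Socs2, 3 for Mcm7 and 4 each for Hrh2, Hoxb6, Fasn and Rps14, and 3 BM arrays for Ccna2. Differences with values under each array's floor raised to it were 3.20 for Socs2, 2.80 for Mcm7 and 4.10 for Hrh2. They were 2.56 for Hoxb6, 1.22 for Fasn and 2.26 for Rps14.

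Of the markers of other cells, positive members were 2 of 6 for CD4 T cells, 2 of 10 for NK cells, 9 of 17 for B cells, 3 of 5 for plasma cells, 10 of 24 for neutrophils and 8 of 17 for macrophages. They were 7 of 10 for dendritic cells, 8 of 15 for erythroid cells, 3 of 7 for megakaryocytes, 5 of 8 for mast cells, basophils and eosinophils, where Epx had 2.32, 4 of 7 for progenitors and 8 of 11 for stroma. Camera called 0 of 31 lists (lowest adjusted p of 0.819), with 1 at an unadjusted p under 0.05, the inhibitory and costimulatory receptors. Camera called 0 with an estimated correlation too (lowest adjusted p = 0.988), and fry called 0 in one direction (0.544) and 0 in either direction (0.441). Adjusted over the list alone, 0 members of any list passed, as over all genes.

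BM arrays lay on both slides and LN arrays on slide 1 only. With slide as a fixed term, which equals the difference within slide 1, that of Eif4ebp3 was 2.6, of Esrrb -1.46, of Gsto2 1.69 and of Mcm7 3.41, and the median of the inhibitory and costimulatory receptors was -0.24, while 10 of the 31 list medians took the other sign. Socs2 then had 1.98 and Rps4x -1.08, and of 23 named differences without a bound 4 were smaller by over 1.5 times or turned and 1 was larger. After normexp correction 1 list median took the other sign, and 8 named differences were smaller and 1 larger by as much, where Eif4ebp3 had 1.41, Gsto2 1.07 and Mcm7 1.96. List medians of the other sign were 7 with quantile normalization, 6 scaled to the median and 8 in the deposited table. Scaled to probes above background on all arrays, they were 5. The fixed term called 0 features, slide 1 alone 1 feature, named only by its probe, and leaving out LN replicate 5 called 2 features, 1 of them Peg3. Without BM replicate 4 Socs2 had 2.31, without LN replicate 4 Tnfrsf4 had -0.91, and without BM replicate 1 Rps14 had 1.47.

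BM cells were then compared with the uninjected lymph node cells. Naprt1, an enzyme that makes NAD from nicotinic acid (15:75721400-75721459), had -2.20 ± 0.40 in BM and 1.01 ± 1.47 in NTc, a log2 difference of -3.21 (95% confidence interval -4.52 to -1.89; limma adjusted p of 0.350). Insl5, a peptide hormone of the insulin family (4:102690720-102690779), had 0.81 ± 0.53 in BM and 2.73 ± 0.45 in NTc (adjusted p of 0.350). Irs1, an adaptor of the insulin receptor (1:82233564-82233623), was well above background on 4 BM arrays and 0 NTc arrays and was at least 6.06-fold higher in BM (adjusted p of 0.50). That bound was 14.01-fold without BM replicate 4, the array not above background, and 4.04-fold without BM replicate 5. Limma called 0 of 25575 features, with 1907 (7.46%) at an unadjusted p under 0.05, of which 1018 were higher in BM and 889 in NTc. The groups did not overlap for 299 features (1.18%), where chance gives 0.794%.

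Other features on the BM side were Golga5, a Golgi protein, at least 2.44-fold higher, Spin4 at least 1.44-fold and Aff1, a scaffold of transcription elongation, at least 1.36-fold, each with 4 BM arrays and 0 NTc arrays well above background. Cwf19l1 had 2.80 ± 1.09 in BM and 0.45 ± 0.59 in NTc. On the NTc side were Ahrr, the repressor of the aryl hydrocarbon receptor, with a difference of -3.62 and 1 BM array well above background, the protease Adam8, at least 2.05-fold higher in NTc, and Prss39, a serine protease, at least 1.81-fold, the last 2 with 4 NTc arrays and 0 BM arrays well above background. With values under each array's floor raised to it, Ahrr had -2.41. Their adjusted p lay between 0.350 and 0.50.

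Among the lists, the DNA replication gene Mcm7 had -0.23 ± 1.51 in BM and -3.80 ± 1.75 in NTc, a difference of 3.57, and passed when adjusted over the list alone (limma adjusted p of 0.0358), though not over all genes (0.50). Ms4a1, which encodes the B cell protein CD20, had -2.80 ± 0.54 in BM and -4.97 ± 1.27 in NTc and also passed when adjusted over the list alone (0.0295) but not over all genes (0.50). With 2 NTc arrays well above background for Ms4a1 and 3 for Mcm7, their differences were 0.91 and 2.80 when values under each array's floor were raised to it, against 2.18 and 3.57. Ms4a1 was 1 of 9 positive members among 17 B cell markers, whose median difference was 0.02. Those 2 were the members that passed in this comparison over their lists, and 0 passed over all genes. The p-values over a list alone were not adjusted over the 31 lists, so a few such passes can arise by chance. All 8 mast cell, basophil and eosinophil markers were positive (median 0.52), with Tpsb2, a mast cell tryptase, at 4.29 ± 0.48 in BM and 2.07 ± 2.17 in NTc. Of the dendritic cell markers 9 of 10 were positive, with a median of 0.39.

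Positive members were 8 of 22 for effector molecules, where Srgn had -1.93, 10 of 16 for naive and resting T cells, 12 of 23 for transcription factors, 5 of 12 for inhibitory and costimulatory receptors and 14 of 26 for cytokines. The inhibitory receptor gene Pdcd1 had -1.77, with BM replicate 2 apart at -6.48. For homing receptors they were 14 of 27, where S1pr5 had 2.03 and Ccr8 -1.11. They were 11 of 20 for DNA replication, 12 of 28 for mitosis, where Ube2c had -1.82, 6 of 17 for glycolysis, where Tpi1 had 2.16, 19 of 36 for oxidative phosphorylation, where Cox6c had 1.91, and 11 of 23 for fatty acid and lipid genes, where Fdft1 had -1.83. For type I interferon they were 12 of 32, where the antiviral gene Mx2 had 2.09 and Usp18, which restrains interferon signalling, had -1.60. They were 7 of 13 for hypoxia, 13 of 25 for immediate early and NF-kB genes, 14 of 24 for heat shock, where Chac1 had -0.93, 6 of 17 for apoptosis, 25 of 53 for ribosomal proteins, where Rpl38 had 1.38, and 3 of 9 for TGF-beta and residence.

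Markers of T cell identity had 6 of 17 positive members, CD4 T cells 3 of 6, NK cells 6 of 10, plasma cells 4 of 5, neutrophils 11 of 24, where Chi3l3 had -1.40, and macrophages 7 of 17. Erythroid cells had 8 of 15, megakaryocytes 3 of 7, progenitors 4 of 7 and stroma 3 of 11. Among the genes named here, BM arrays well above background were 2 for Pdcd1, 3 for Srgn and Chi3l3 and 4 for Chac1, and NTc arrays were 2 for S1pr5 and Mx2 and 4 for Pdcd1 and Chi3l3. Differences with values under each array's floor raised to it were -1.41 for Pdcd1, -1.43 for Srgn and -1.09 for Chi3l3. They were -0.91 for Chac1, 1.36 for S1pr5 and 1.95 for Mx2. Camera called 0 of 31 lists (lowest adjusted p of 0.476), with 2 at an unadjusted p under 0.05, the dendritic cell and the mast cell markers. With an estimated correlation it called 0 (lowest adjusted p = 0.751), and fry called 0 in one direction (0.479) and 0 in either (0.132).

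Within slide 2, which equals the value with slide as a fixed term, the difference of Naprt1 was -3.31, of Insl5 -1.82 and of Mcm7 2.92, and the medians of the mast cell and dendritic cell lists were 0.21 and 0.60, while 6 of the 31 list medians took the other sign. Srgn then had -0.66, S1pr5 1.34, Cox6c 2.92 and Chi3l3 -2.48, and of 24 named differences without a bound 5 were smaller by over 1.5 times or turned and 3 were larger. After normexp correction 9 were smaller and 2 larger by as much, with Mcm7 at 2.02 and Ms4a1 at 0.39. Then 12 of the 31 list medians took the other sign, among them naive T cells with -0.033 and cytokines with -0.098, and the mast cell and dendritic cell medians were 0.24 and 0.38. Adjusted over the list alone, neither Mcm7 (limma adjusted p of 0.539) nor Ms4a1 (0.140) passed with slide as a fixed term, and Ms4a1 did not after normexp correction (0.664). The difference of Ms4a1 with slide as a fixed term was 2.39. Leaving out each of the 15 arrays in turn, each of the 2 passed in 9 fits. Fits without an LN array left both differences unchanged and moved only the shared spread, so passes there say little. Of the BM and NTc arrays, leaving out BM replicate 3 or 5 or NTc replicate 2 or 3 let both pass. Mcm7 also passed without NTc replicate 1. Without any other BM or NTc array neither passed. The fixed term called 1 feature, Ppp6r3, named after its values were seen, and slide 2 alone 0. Leaving out NTc replicate 5 called 4 features, Naprt1 and Adam8 among them, leaving out BM replicate 4 called Irs1, and leaving out BM replicate 5 called 1 predicted gene. Without NTc replicate 1 Tpsb2 had 1.45. Of the features at an unadjusted p under 0.05, 53.4% were higher in BM, against 39.3% after normexp correction and 65.7% when scaled to probes above background on all arrays, which moved the median of all features by 0.103.

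LN cells and uninjected lymph node cells came from the same kind of organ. Naprt1 had -3.03 ± 0.86 in LN and 1.01 ± 1.47 in NTc, a log2 difference of -4.04 (95% confidence interval -5.35 to -2.72; limma adjusted p of 0.0819). Insl5 had 0.30 ± 0.49 in LN and 2.73 ± 0.45 in NTc, a difference of -2.43 (-3.24 to -1.63; adjusted p of 0.0819). Irs1 was well above background on 5 LN arrays and 0 NTc arrays and was at least 9.10-fold higher in LN (adjusted p of 0.198). Limma called 0 of 25575 features, with 2327 (9.10%) at an unadjusted p under 0.05, of which 1298 were higher in LN and 1029 in NTc. The groups did not overlap for 446 features (1.75%), where chance gives 0.794%.

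On the LN side were also Ncald, a calcium sensor, at least 6.02-fold higher and Aff1 at least 1.62-fold, both with 0 NTc arrays well above background, the synaptic adhesion gene Nlgn2 with 2.70 and 1 NTc array well above background, and Musk, a kinase of the neuromuscular junction, with 1.75 ± 0.27 in LN and 0.27 ± 0.41 in NTc. On the NTc side were Ip6k3, an inositol phosphate kinase, at least 11.4-fold higher, and Srr, serine racemase, at least 4.76-fold, both with 0 LN arrays well above background, and Fscn2, an actin bundling protein of the retina, with -3.28 and 3 LN arrays well above background. With values under each array's floor raised to it, Nlgn2 had 1.03 and Fscn2 -2.91. In NTc replicate 5, the array not well above background, the level of Ip6k3 was -5.72, while the other 4 NTc arrays lay between -0.27 and 0.57. The Ip6k3 bound was 25.9-fold without NTc replicate 5 and 8.71-fold without NTc replicate 4. The adjusted p of these 7 lay between 0.178 and 0.303.

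**Figure D2:**
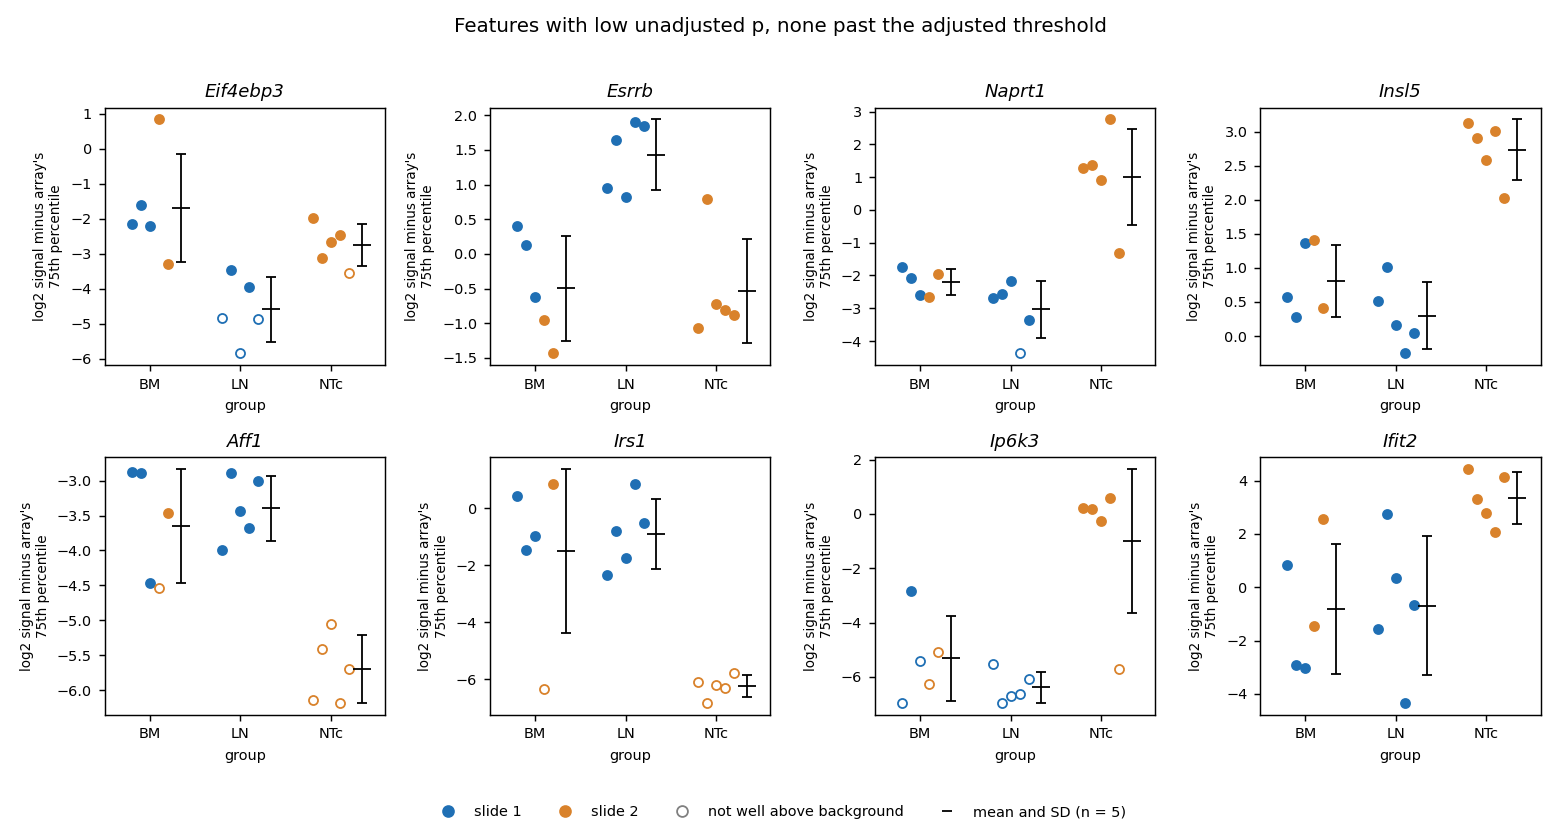
Level of 8 genes on each array (vertical axis, log2 units relative to the array's 75th percentile) in the BM, LN and NTc groups. Points are arrays, coloured by slide and open where the probe was not well above background, and bars are the mean and SD of 5 arrays. None passed the threshold, and Naprt1 and Insl5 lie higher in NTc (means of 1.01 and 2.73) than in BM (-2.20 and 0.81) and LN (-3.03 and 0.30).

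Of the mitosis genes 15 of 28 had a positive LN minus NTc difference, while Ccna2, which encodes cyclin A2, was at least 2.29-fold higher in NTc and passed when adjusted over the list alone (limma adjusted p of 0.0188) but not over all genes (0.304). Of the stroma and endothelium markers 3 of 11 were positive, with a median of -0.64, and the chemokine gene Cxcl12 had -2.45 ± 0.94 in LN and -0.46 ± 0.48 in NTc, which passed adjusted over the list alone (0.0365) but not over all genes (0.351). Those 2 were the members that passed over their lists, again without adjustment over the 31 lists, so that chance can give a few such passes. Of the type I interferon genes 12 of 32 were positive, among them Zbp1 with 1.21, while the interferon-induced Ifit2 had -0.69 ± 2.6 in LN and 3.35 ± 0.96 in NTc. Effector molecules had 7 of 22, with the granzyme gene Gzmg at -4.46 ± 1.13 in LN and -2.5 ± 0.61 in NTc. T cell identity had 9 of 17, with Thy1 at 1.73 ± 0.36 and 3.33 ± 1.04.

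Positive members were 9 of 16 for naive and resting T cells, 8 of 23 for transcription factors, where Prdm1 had 0.86, and 6 of 12 for inhibitory and costimulatory receptors, where Cd244 had 1.47. They were 11 of 27 for homing receptors, where the integrin gene Itgav had 2.6, and 15 of 26 for cytokines, where Il2 had 1.32 and Il18r1 -1.60. They were 12 of 20 for DNA replication, where Uhrf1 had 1.82, while the mitosis gene Spc25 had 1.57. For glycolysis they were 5 of 17, where Aldoc had -1.15, for oxidative phosphorylation 17 of 36, for fatty acid and lipid genes 11 of 23, where Cpt1a had -1.95, and for hypoxia 5 of 13, where Vegfa had 1.99. They were 14 of 25 for immediate early and NF-kB genes, where Klf4 had 2.99 and Klf6 -2.47, 11 of 24 for heat shock, where Hspa1a had -1.85, 5 of 17 for apoptosis, where Cflar had -1.18, and 2 of 9 for TGF-beta and residence, where Skil had 1.27. For ribosomal proteins they were 25 of 53, where Rps4x had 1.96.

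Markers of CD4 T cells had 4 of 6 positive members, NK cells 6 of 10, B cells 5 of 17, plasma cells 5 of 5, neutrophils 10 of 24, where Pglyrp1 had 3.29, and macrophages 11 of 17. Dendritic cells had 7 of 10, erythroid cells 5 of 15, megakaryocytes 3 of 7, mast cells 4 of 8, where Tpsb2 had 2.30, and progenitors 4 of 7. Among the genes named here, LN arrays well above background were 2 for Klf6, 3 for Gzmg and 4 for Naprt1, and NTc arrays were 2 for Il2 and Vegfa and 4 for Klf4, Klf6 and Pglyrp1. Differences with values under each array's floor raised to it were -2.13 for Klf6, -1.58 for Gzmg, 0.96 for Il2, 1.44 for Vegfa and 2.53 for Klf4. Those of Naprt1 and Pglyrp1 did not change. Camera called 0 of 31 lists (lowest adjusted p of 0.863), with 1 at an unadjusted p under 0.05, stroma and endothelium. With an estimated correlation it called 0 (lowest adjusted p = 0.997), and fry called 0 in one direction (0.347) and 0 in either (0.0986). The signs of the median, the mean and camera's direction were not all the same for cytokines and progenitors in each comparison. This also held for DNA replication and megakaryocytes in BM against LN. In BM against NTc it held for transcription factors, oxidative phosphorylation, fatty acid genes, immediate early genes, apoptosis, ribosomal proteins, macrophages and megakaryocytes. In LN against NTc it held for inhibitory and costimulatory receptors, homing receptors, fatty acid genes, hypoxia, ribosomal proteins, T cell identity, neutrophils and megakaryocytes.

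No slide held both groups. With slide as a fixed term, linked through the BM arrays, Naprt1 had -4.21, Insl5 -2.26, Cxcl12 -2.45 and Ifit2 -1.78, and 5.64% of features had an unadjusted p under 0.05. The median of the stroma list was then -0.86, 15 of the 31 list medians took the other sign, and so did Aldoc with 0.34, Rps4x with -0.24 and Pglyrp1 with -0.25. Of 32 named differences without a bound, 16 were smaller by over 1.5 times or turned, with Il2 at 0.28, Il18r1 at -0.75, Skil at 0.27, Spc25 at 0.41, Zbp1 at 0.36 and Itgav at 1.32. The 2 larger by as much were Vegfa with 3.90 and Klf6 with -5.00. After normexp correction 8 list medians took the other sign, and 7 named differences were smaller and 2 larger, with Vegfa at 0.46 and Cxcl12 at -1.39. Adjusted over the list alone, neither Ccna2 (limma adjusted p of 0.904) nor Cxcl12 (0.313) passed with slide as a fixed term, and Ccna2 did not after normexp correction (0.320). Leaving out each of the 15 arrays in turn, Ccna2 passed in 9 fits and Cxcl12 in 6. Fits without a BM array left both differences unchanged and moved only the shared spread, so passes there say little. Of the fits without an LN or NTc array, Cxcl12 passed only in that without LN replicate 3 (limma adjusted p of 0.0143). The fixed term called 2 features, Ppp6r3 and a RIKEN clone, both named after their values were seen, and fitting LN and NTc alone called 3, Irs1 among them. Leaving out NTc replicate 5 called 5 features, Naprt1, Insl5 and Ip6k3 among them, leaving out BM replicate 2 or BM replicate 4 called 2 each, and leaving out LN replicate 5 called Peg3. Without NTc replicate 1 Klf4 had 1.82, Tpsb2 1.53 and Il18r1 -1.07. Of the features at an unadjusted p under 0.05, 55.8% were higher in LN, against 43.4% after normexp correction.

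Both comparisons with NTc used the same 5 control arrays. Limma called 0 features in both. Across features their log2 differences correlated at r of 0.612, where simulated unchanged groups against the same controls gave 0.50, and the covariance was 0.467 against a simulated 0.290, a difference of 0.177. With the controls split between the comparisons r was 0.159 and the covariance 0.170. The sign was shared by 72.5% of features, against 66.7% simulated. At an unadjusted p under 0.05, 425 features were higher and 337 lower in both, where simulated unchanged groups against the same controls gave 113 to 171 and 119 to 170 over 20 simulations. The 20 simulations drew each feature independently, so the range of their counts can be too narrow where features vary together. The simulated values hold no slide difference, while the 5 LN arrays and 3 of the 5 BM arrays lay on slide 1 and the 5 NTc arrays on slide 2.

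The level of a probe followed its base composition. Across probes, Spearman's rho between the count of G and C bases and the level lay between 0.506 and 0.548 on the 15 arrays, where probes are not independent replicates. Probes with 21 G or C bases had a median level of -5.41, those with 27 had -1.95 and those with 33 had 0.46.

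**Figure D3:**
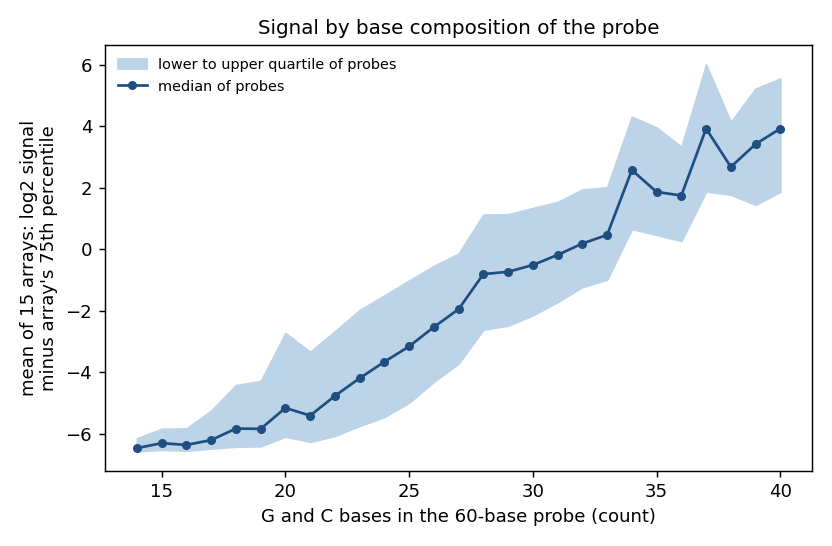
Median level of probes (vertical axis, log2 units relative to the array's 75th percentile, mean of 15 arrays) by the count of G and C bases in the 60-base probe (horizontal axis), with the quartiles of the probes at each count. The median climbs from -5.41 at 21 bases to 0.46 at 33.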

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

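The tests of base composition, of probes of the same gene, of repeat probes, of array brightness as a covariate and of counts of called features or lists over other splits were chosen after the results were seen.

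No feature passed limma's threshold, with 0 called in each comparison and 1268, 1907 and 2327 at an unadjusted p under 0.05 for BM against LN, BM against NTc and LN against NTc. Whether brightness came from the named transcript stays open. Spearman's rho across probes between the count of G and C bases and the mean level was 0.574. Mean levels of 2 probes of the same gene correlated at r of 0.142. For pairs within 300 bp that r was 0.309, for those of them 60 bp or more apart 0.173, and for pairs farther apart 0.095. The rho of 0.574 and the r of 0.142 met the limits first written for a signal not set by the transcript. Probes of unlike affinity could give such values too, which was not tested. With base counts centred 0 features were called (1261, 1831 and 2322 at an unadjusted p under 0.05). A probe has the same base count on every array, so an effect common to all arrays cancels in a group difference. That fit therefore cannot decide whether base composition set the signal. Uneven amplification of a little mRNA stays open, since the deviations of 2 probes of a gene within 300 bp correlated at a median r of 0.218, though at 0.0906 (0.0442 to 0.141) where they lay 60 bp or more apart, and so does the number of arrays, at which 58.9% of simulated 8-fold changes were recovered. That the groups differ little in their biology also stays open, as untested. A real count of 0 is reached by any split, so the 100 of 100 splits drawn of 126 that called as many features and lists say nothing about chance, and the highest of the other splits called 2, 1 and 6 features and 2, 1 and 1 lists for BM with LN, BM with NTc and LN with NTc.

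LN against NTc held 9.10% of features at an unadjusted p under 0.05. Of 100 splits, 2 gave as many, the real one included (real 2327, highest other 2755). That share of 0.02 lay under the limit of 0.05 written before the data were seen, which held no adjustment over comparisons. It became 0.06 when adjusted over the 3 comparisons, so chance cannot be excluded. The outcome also depends on which 100 of the 126 splits were drawn. A difference between the slides could account for the 9.10%, as LN and NTc lay on different slides. Their difference correlated across features at r of 0.143 with BM slide 1 minus BM slide 2. The highest of the other BM splits gave 0.128, and 10 splits are too few for a share under 0.05. The share of features at an unadjusted p under 0.05 was 5.64% with slide as a fixed term. That term links the groups only through the BM arrays and widens the standard errors. The share could thus fall with the differences unchanged, and its fall does not decide the question. Array brightness cannot be told apart from the groups, because NTc arrays were dimmer on average, the highest other split was the 5 brightest against the 5 dimmest arrays, and with brightness as a covariate the share was 6.01%. A response to the injected antigen stays open as well, as untested.

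For features in the other comparisons and for lists at an unadjusted p under 0.05, chance cannot be excluded either. In BM against LN 23 of 100 splits gave as many features (real 1268, highest other 1918), and in BM against NTc 8 of 100 did (real 1907, highest other 2836). For lists 68 of 100 splits gave as many in BM against LN (real 1, highest other 5), 42 in BM against NTc (real 2, highest other 5) and 77 in LN against NTc (real 1, highest other 4).

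Probes with a GT or CA dinucleotide repeat were among the brightest, with 107 of 110 such probes in the top 500 by mean level. The count of G and C bases is argued against as the reason, since their median level lay 12.03 log2 units above probes of the same count. No biological explanation was tested.

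In 6 of 177 groups of 5 values tested, 1 array lay far from the other 4, judged by its gap to the nearest as a share of the range, and chance gives about 8.85 such groups. Ip6k3 in NTc had a share of 0.866 (NTc replicate 5 at -5.72, the others -0.27 to 0.57). Spin4 in BM had 0.828 (BM replicate 2 at -4.90, the others -3.39 to -3.08). Rps14 in BM had 0.796 (BM replicate 1 at 1.37, the others -3.06 to -2.16). Tnfrsf4 in LN had 0.780 (LN replicate 4 at 3.48, the others 0.32 to 1.02), and Pdcd1 in BM had 0.761 (BM replicate 2 at -6.48, the others -4.52 to -3.91). The number of outlier spots in LN had 0.866 (LN replicate 5 with 240, the others with 143 to 156).

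Control probes outside the comparisons carried signal. The 96 probes of the ERCC spike-in sequences had a median signal of 24.2 on the dimmest array, NTc replicate 1, and the 10 probes of the E1A spike-in had 42.9 there, while the negative control lay between 3.54 and 6.05 on the 15 arrays. Whether spike-in RNA was added is not given in the sources used here.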

How the results depend on the processing

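Chosen after the data were seen were the alternatives by base count, lists over every probe, array brightness and leaving out the 2 least correlated arrays. Between 55.6% and 71.2% of probes per array were well above background. For the 7 counts of called features or lists, 232 of 251 values under alternatives equalled the 0 reported and 19 did not. The cause of those 19 was not tested. The lowest adjusted p over alternatives ranged from 0.0205 to 0.99998 for features in BM against LN, 0.00174 to 0.553 in BM against NTc and 0.00178 to 0.422 in LN against NTc, and for lists from 0.0327 to 0.988, 0.00692 to 0.993 and 0.218 to 0.997. With slide as a fixed term 1 feature was called in BM against NTc (Ppp6r3, named after its values were seen), 2 in LN against NTc and 1 in both, and slide 1 alone called 1 in BM against LN. No slide held both LN and NTc, so that comparison has no value within a slide. With only the 2 groups compared, 3 were called in LN against NTc. Probes with fewer than 24 G or C bases gave 1 feature in LN against NTc and 1 list in BM against NTc, ribosomal proteins (16 of 22 probes higher in BM, median 0.77, adjusted p = 0.00692, and 0.144 with an estimated correlation). Every probe with base counts centred gave 2 lists in BM against LN, inhibitory and costimulatory receptors (4 of 16 probes higher in BM, median -0.36) and glycolysis (21 of 31, median 0.26), each at an adjusted p = 0.0327, and 0.0945 with an estimated correlation. Leaving out 1 array gave 0 to 2 features in BM against LN (2 without LN replicate 5), 0 to 4 in BM against NTc (4 without NTc replicate 5, 1 each without BM replicate 4 or 5), 0 to 5 in LN against NTc (5 without NTc replicate 5, 2 each without BM replicate 2 or 4, 1 without LN replicate 5) and 0 to 3 in both (3 without NTc replicate 5, 1 without BM replicate 4), with 0 lists throughout. Without LN replicate 3 and NTc replicate 1, the least correlated, limma called 0 features, with 1277, 1622 and 1670 at an unadjusted p under 0.05, and with brightness as a covariate 0, with 1370, 1342 and 1538.

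With the replicate number as a block, limma called 1 feature in LN against NTc (Gm12372, named after its values were seen), and 0 features in the other comparisons and 0 lists, as without the block. Over 15 pairs of samples with the same number, deviations from group means correlated between -0.11 and 0.092, and in 2 of 15 pairs the first sample correlated best with its own number, so the data give no hint of pairing.

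Of 2782 values of 94 named log2 differences, 2729 kept their direction, 53 took the other sign and 9 passed the threshold (Irs1, Peg3, Naprt1, Adam8, Insl5 and Ip6k3). The cause of the turns was not tested. Apart from the sorting markers, these differences were chosen for a low p on the same arrays. Leaving out an array of the group not compared leaves a difference as it was. The number that kept their direction is thus partly given in advance. Cd8b1 in BM against LN had -0.028 with quantile normalization, -0.013 scaled to the median, -0.024 in the deposited table, -0.073 with base counts centred and -0.062 with brightness. Cd44 in BM against NTc had -0.025 scaled to the median and -0.017 with base counts centred, and Cd8b1 there had 0.0029 scaled to probes above background on all arrays. With slide as a fixed term, and alike on slide 1 only, BM against LN had 0.34 for Cd8a and -0.043 for Cd8b1. BM against NTc had, with that term and alike on slide 2 only, 0.018 for Cd8b1 and -0.013 for Cd44. LN against NTc with that term had 0.34 for Aldoc, -0.24 for Rps4x, -0.25 for Pglyrp1, -2.24 for Cd8a, 0.060 for Cd8b1 and 0.33 for Cd3e. Array weights gave Cd8a -0.55 in LN against NTc. Without the 2 least correlated arrays Cd8a had 0.14 in BM against LN and -1.07 in LN against NTc, and Cd44 had -0.091 in BM against NTc. With brightness as a covariate BM against NTc had 0.25 for Cd8b1 and 0.046 for Cd3e, and LN against NTc had -1.63 for Cd8a, 0.31 for Cd8b1 and 0.54 for Cd3e. Leaving out 1 array, BM against LN ranged from -1.79 to 0.14 for Cd8a, -0.13 to 0.39 for Cd8b1 and -0.48 to 0.14 for Cd3e. BM against NTc then ranged from -1.05 to 0.19 for Cd8a, -0.27 to 0.11 for Cd8b1 and -0.091 to 0.15 for Cd44, and LN against NTc from -0.65 to 1.28 for Cd8a, -0.49 to 0.077 for Cd8b1 and -1.06 to -0.45 for Cd3e.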

Other observations

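The genes, the distances between probes and the splits by brightness given here were chosen after the results were seen. Probes of several T cell genes were well above background on 15 arrays, among them Ptprc, Lck, Cd3g, Thy1, Gzma, Prf1 and Ifng. Others were not, with 0 arrays for Gzmb, a granzyme, Il7r, the interleukin 7 receptor, and Tmsb4x, an actin-binding peptide, 2 arrays for B2m, a subunit of the major histocompatibility molecule, 3 for the T cell receptor chain Cd3d, and 1 and 0 for the 2 probes of the T cell factor Tcf7. Genes of other tissues were among those well above background on 15 arrays, with Ins2, an insulin gene, Krt5, a keratin of skin, and Myh6, a myosin of heart muscle, while S100a8 of neutrophils had 0 arrays and Alb, albumin of liver, 4. Base composition differed between these probes, with 19 G or C bases for B2m, 21 for Il7r, 22 for Tmsb4x and 23 for Gzmb, against 29 for Ins2 and 33 for Prf1 and Ptprc. Gzma with 23, Ifng and Cd3g with 24 and Cd3d with 32 went the other way. Probes with 19 such bases were well above background in 28.4% of cases and those with 33 in 96.5%. Detection of a probe here is thus not a measure of the cells' transcripts alone. Per array, 55.6% (NTc replicate 5) to 71.2% (BM replicate 1) of all probes were well above background. The median level of each fixed list was set against 10000 random lists of genes whose probes had the same counts of G and C bases. The first probe listed for each gene was used. T cell identity stood at percentile 88.9, effector molecules at 51.25 and naive and resting T cells at 25.3. Over all lists the percentiles ran from 6.13 (TGF-beta and residence) to 96.3 (immediate early and NF-kB genes). The genes named here thus do not show T cell lists to be brighter than random ones of the same base counts.

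The 615 probe pairs of a gene within 300 bp, whose deviations correlated at a median r of 0.218, had a bootstrap interval of 0.169 to 0.275. For the 387 of these at least 60 bp apart the median was 0.0906 (0.0442 to 0.141). Over 2585 pairs farther apart than 300 bp it was 0.0165, and for random pairs 0.00311.

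Over the other splits drawn, the median count at an unadjusted p under 0.05 was 1153, 1217 and 1214 for BM with LN, BM with NTc and LN with NTc. The 5 brightest against the 5 dimmest arrays gave 1745, 2836 and 2755, all above those medians, and the reason was not tested. Floors also differed between arrays, from -5.01 in BM replicate 1 to -3.52 in NTc replicate 5 relative to the array's 75th percentile. Brightness, slide and group are not separated by these splits, since the 5 brightest held 3 of the 3 slide 1 arrays in BM with NTc and 4 of the 5 in LN with NTc. The mean log2 75th percentile of signal was 8.74 in BM, 8.87 in LN and 8.28 in NTc. The exact two-sided p over 252 splits was 0.492, 0.0873 and 0.0397 for BM against LN, BM against NTc and LN against NTc, and adjusted 0.492, 0.131 and 0.119.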
